A study of Homo sapiens with 16 samples.

How the data were processed

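The 16 libraries were prepared from poly(A) RNA with a stranded kit, per the labels' protocols, from SW480 and SW620 cells grown in DMEM with serum. Groups and replicate numbers came from the labels. The authors deposited a table of read counts per gene and a table of FPKM values per gene, each with 16 columns for the 16 libraries and 0 other columns of per-sample values. Per the submitters' processing notes, TopHat2 2.0.4, SAMtools, Picard 1.29, HTSeq 0.6.1 and Cufflinks 2.1.1 were used with the human build GRCh37; which tool made which table is not given in the sources used here, nor whether counting used the strand. The deposited counts were whole numbers that differed in their totals between libraries, so they were treated as raw read counts. The FPKM values, read levels scaled by transcript length and library size as the authors deposited them, entered only as an alternative. The reference annotation at hand was of another build than GRCh37, so no coordinates are given.

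The count table held 63677 gene identifiers and 0 lines that name no gene. Gene symbols came from the FPKM table, which held 63655 of these identifiers, so that 22 were without an FPKM value; 31 symbols that had been turned into dates were replaced by those of the reference annotation. GC content and length of transcripts came from the reference annotation and were known for 98% of the genes tested. Transcript order along chromosomes from the same annotation was used for windows of neighbouring genes, without coordinates. Genes with a near-identical copy are named as uncertain.

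The design, the tests, 31 gene lists and the rule for the genes named were fixed before the data were examined. Counts were filtered with edgeR's filterByExpr, which left 17464 genes, scaled with TMM factors and fitted with 1 quasi-likelihood model over all 16 libraries with 8 groups of 2 and no further covariate, so that all groups shared 1 estimate of the spread (edgeR 4.0.16, R 4.3.3). The TMM factors ran from 0.585 to 1.36, and the 10 most abundant genes took 4.65 to 10.6% of the reads of a library. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and p-values are two-sided. SEs of log2 fold changes were derived from the quasi-likelihood F statistic. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the libraries, with adjustment over the 30 lists that had 3 or more tested genes; 36 of 779 list genes were on several lists. The 2 kinds of adjusted p are both printed, because the estimated correlation ended many list calls.

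Genes were named by a rule: ESR2 first; then, of the called genes with a mean of 5 CPM or more in the higher group and both libraries of one group above both of the other, up to 8 per direction with the largest log2 fold change; then up to 3 called members per list with the smallest p. With 2 libraries against 2, chance alone separates the groups for 33.3% of genes. Clone-style and antisense names, pseudogenes and sex-linked control genes were left out, and some genes that the rule named are not reported here. Genes named from fits of fewer libraries were chosen after their values were seen. Levels are means ± SD of TMM-scaled CPM, except for ESR2, which is given as CPM of the library total. Where a group had 0 reads of a gene, the fold is a bound computed from library totals against a floor of 3 reads over the group; 3 reads equal 0.16 to 0.24 CPM of a single library. With 1 to 3 reads, the ratio is given with an exact 95% counting interval. Medians of lists were recomputed with genes without reads at their bound: of 210 medians, 5 moved by over 0.05, and among the 55 that belong to a list past the camera test the largest move was 0.04.

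Alternatives fixed beforehand were RLE size factors, no low-count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1 and without a filter on low values, a fit of the groups of the comparison alone, a replicate block, a minimum of 2-fold, parental controls in place of empty vector, and leaving out each library in turn. When a library was left out, the lone library of its group was assumed to vary like the other groups. After the data were seen, 3 kinds of fit were added: offsets that remove each library's smooth trend with transcript GC content and length (natural splines with 5 degrees of freedom each), fits of the libraries of 1 line only, and both together. The test of the vector effect between lines, estradiol against no treatment, the marker genes of the parental lines, the windows of 40 neighbouring genes and all weighing of explanations were also added then.

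Simulated data were used to test edgeR for ERB in each line and for estradiol, the GC offsets, the marker shares, the windows and the list test. The other comparisons and the alternative tests were not simulated. For edgeR, the offsets and the list test, counts were drawn independently per gene, with means, library sizes and dispersions from the fit of 16 or of 10 SW620 libraries. Changed genes came only from those with a mean expected count of 50 or more. No GC trend between libraries of a group was simulated. For ERB in SW480 the spread was that of all 16 libraries, with a common coefficient of variation of 0.36. It was 0.534 in the 6 SW480 libraries alone, so false calls from too small a spread there could not show. For ERB in SW620, the fit of 16 libraries over 17464 genes recovered 0% of genes changed 1.5-fold, 4% at 2-fold, 26% at 4-fold and 90% at 8-fold, with 0 false calls; for ERB in SW480 the values were 0%, 0%, 16% and 70%, with 0 false calls. The fit of 10 SW620 libraries over 16533 genes recovered 34% at 2-fold and 96% at 4-fold for ERB in SW620, with 6 false calls, and 40% and 96% for estradiol, with 9. With a simulated GC trend in the estradiol comparison, over 16216 genes, 4872 false calls arose without offsets and 12 with them. Marker shares of 10, 20 and 50% were estimated as 11.9, 22.4 and 52.4%, in mixtures of parental libraries that also served to choose the markers. On chromosome windows, slopes of 0 and 0.8 in simulated normal values, not counts, were recovered as 0.03 and 0.81. In the simulated list test, 1 of 1 list changed 4-fold and 0 of 19 unchanged lists were called. Its genes were independent, so it says nothing about lists of correlated genes.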

Results

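Messenger RNA from 2 human colon cancer cell lines was sequenced in 16 libraries. SW480 was derived from a primary colon tumour and SW620 from a lymph node metastasis of the same patient. Each line was sequenced as parental cells, after transduction with an empty vector and after transduction with ESR2, the gene of estrogen receptor beta (ERB), a ligand-dependent transcription factor. SW620 cells carrying ERB were also sequenced after 24 h in the solvent DMSO and after 24 h with 10 nM estradiol. These 8 groups held 2 libraries each, numbered I and II in the labels. The total counts of libraries I and II were 14390800 and 14002269 in parental SW620, 17409936 and 17227271 in SW620 with empty vector and 15788126 and 18740158 in SW620 with ERB. With DMSO they were 17369097 and 12743940 and with estradiol 15062156 and 15208424. In SW480 they were 15856301 and 18948283 in parental cells, 13621574 and 15354043 with empty vector and 14104263 and 15407963 with ERB. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between libraries. Libraries of the same group differed beyond counting noise in all 8 groups, most in SW480 with empty vector (chi-square per degree of freedom 280, against 7.2 in SW620 with ERB).

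The transduced gene was examined first. ESR2 (ENSG00000140009) had 162 and 187 reads in the 2 SW620 libraries with ERB, against 1 and 1 with empty vector and 0 and 0 in parental cells. In SW480 it had 142 and 185 reads with ERB, 2 and 4 with empty vector and 2 and 2 in parental cells. Scaled to the library total as CPM, this was 10.1 ± 0.2 (SD, n = 2) in SW620 with ERB and 11 ± 1.4 in SW480 with ERB. The ratio of ERB to empty vector was 175 in SW620 (95% counting interval 48.1 to 1450) and 53.5 in SW480 (24.3 to 147). Against parental SW620 the level was at least 95.7-fold higher, taking a floor of 3 reads over the group, and against parental SW480 it was 96.4-fold higher (37.3 to 356). These intervals and floors, here and further on, cover counting error only. ESR2 stood at 8.67 ± 1.2 CPM after DMSO and 11.1 ± 1.2 CPM after estradiol. The gene of estrogen receptor alpha, ESR1, had 0 reads in all 16 libraries.

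**Figure D1:**
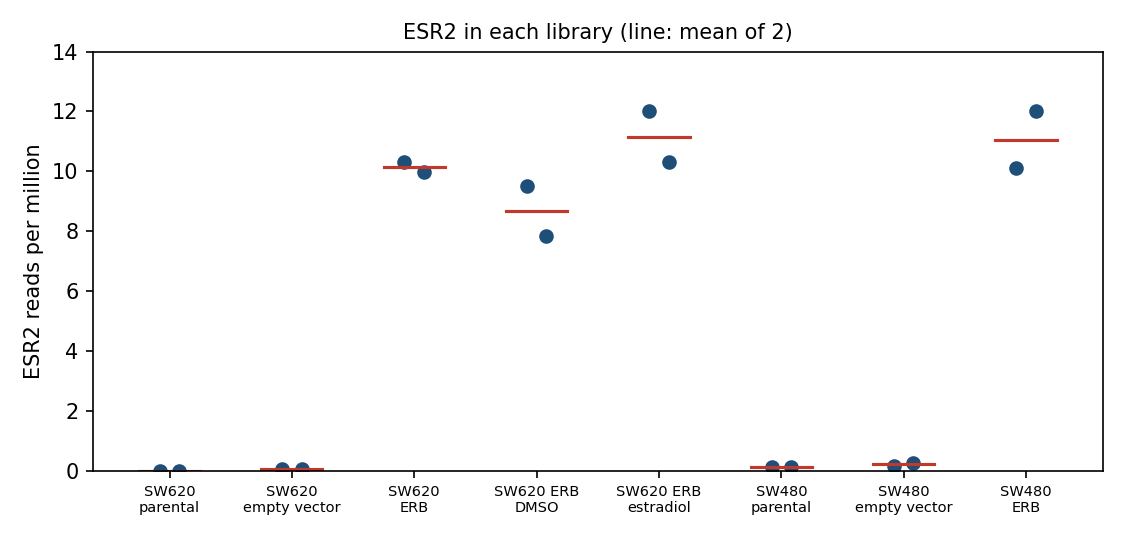
ESR2 level in CPM of the library total (vertical axis) in each of the 16 libraries (points), by group (horizontal axis), with the mean of 2 libraries as a line. The group means of the libraries with ERB lie between 8.67 and 11.1 CPM, and the others at 0.204 CPM or lower.

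How the untreated parental lines differ sets the background for the SW480 comparisons. Parental SW620 had higher levels of genes of the differentiated gut epithelium. VIL1, which encodes the microvillus protein villin, was at 534 ± 63 CPM (SD, n = 2, scaled with TMM factors, as all levels from here on) against 107 ± 6.1 in SW480 (log2 fold change 2.35, SE 0.24, adjusted p = 7.7e-05). HNF4A, an intestinal transcription factor, was at 131 ± 10 against 30 ± 2.7 CPM (2.16, adjusted p = 0.00011). TFF3, a goblet cell peptide, was at 103 ± 38 against 4.13 ± 1 CPM (4.68, SE 0.74, adjusted p = 0.00099). Inflammatory, matrix and adhesion genes were lower in SW620. TNFAIP2, a gene induced by tumour necrosis factor, was at 2.4 ± 0.0013 against 224 ± 5.9 CPM (log2 fold change -6.51, SE 0.45, adjusted p = 8.8e-06), and the matrix protein gene FN1 was at 17.2 ± 3.1 against 560 ± 30 CPM (-4.99).

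In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3147 of 17464 genes between the parental lines, 1194 higher and 1953 lower in SW620. With offsets that remove trends with transcript GC content and length, the split was 3530 higher and 2636 lower. The largest increases were those of the cytokine-like gene CYTL1 (31.7 ± 5.1 against 0.265 ± 0.25 CPM, log2 6.98), PLXNA2 (5.95), the surface glycoprotein gene PROM1 (5.68), CDHR2 (5.61), PRODH2 (4.84), CAPN9 (4.84), the carbonic anhydrase gene CA9 (4.79) and GAL3ST1 (4.73). The largest decreases were in genes without a read in parental SW620. WNT5A, a secreted WNT ligand, was at least 2440-fold lower (219 ± 160 CPM in SW480), GNG11 at least 1780-fold, PHLDB2 at least 1530-fold and IQGAP2 at least 1020-fold. Among the lists of genes, 21 of 28 tested NF-kB and inflammatory targets fell and 0 rose (27 falling and 0 rising adjusted over the list alone; median log2 -3.09; camera adjusted p = 1.9e-20, and adjusted p = 0.00014 with an estimated correlation), with ICAM1 at -7.01 and CXCL1 at -5.11. Of 31 cell-matrix adhesion genes 11 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.0076 with an estimated correlation), among them CYR61 (-5.88) and CTGF (-4.08), both matricellular proteins. Secretory and goblet genes rose, 8 of 12 with 0 falling (9 and 0 adjusted over the list alone; camera adjusted p = 8.3e-07, and adjusted p = 0.0066 with an estimated correlation), with DLL4 at 2.84 and CHGB at 3.44. Of 15 enterocyte genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00012, and adjusted p = 0.026 with an estimated correlation). Mesenchymal genes went both ways, with 11 of 23 falling and 4 rising (11 and 6 adjusted over the list alone; camera adjusted p = 0.0007, but adjusted p = 0.31 with an estimated correlation). Histone genes, a sign of poly(A) selection, had 3 of 13 falling and 0 rising (4 and 0 adjusted over the list alone; median -1.05; camera adjusted p = 0.075), among them HIST1H2BK (-1.26). Fibroblast markers had 2 of 6 falling and 0 rising, also over the list alone (camera adjusted p = 0.16), ACTA2 (-5.65) and COL6A3 (-4.26). The count was 2013 and 1358 without SW620 library I or II and 1837 without SW480 library II.

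Genes that set the parental lines apart were then followed through all groups. For this, 309 genes at 5 CPM or more and at least 8-fold higher in each parental SW480 library than in each parental SW620 library were taken, a set chosen after the values were seen. Their median level, as a percentage of the parental SW480 mean, was 1.39 to 1.97% in the 10 SW620 libraries. In the libraries labelled SW480 with empty vector it was 2.13% in library I and 2.05% in library II, and in those labelled SW480 with ERB 15.5% and 20.5%. In the opposite set, 34 genes high in parental SW620, the libraries labelled SW480 reached 28.4% and 63% of the parental SW620 level with empty vector and 49.4% and 45.6% with ERB, against 4.4% and 5.52% in parental SW480. On these 34 genes the SW620 libraries with empty vector, ERB, DMSO or estradiol ranged from 41.4 to 97.1%.

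**Figure D2:**
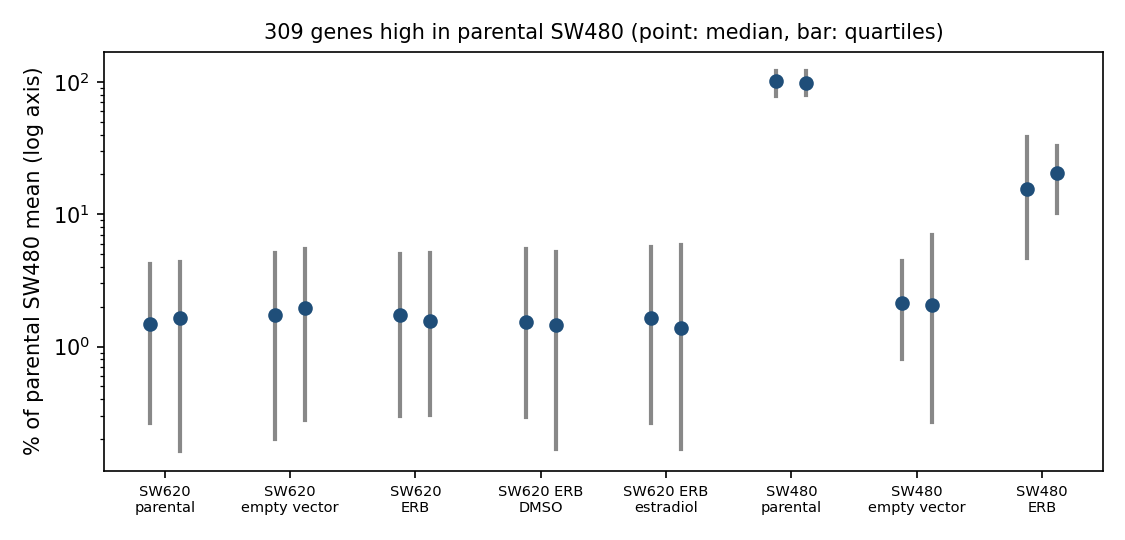
Level of 309 genes high in parental SW480, as a percentage of the parental SW480 mean (vertical axis, logarithmic), in each of the 16 libraries by group (horizontal axis); points are medians over genes and bars span the quartiles. The SW620 libraries sit at medians of 1.39 to 1.97%, the libraries labelled SW480 with empty vector at 2.05 and 2.13%, and those labelled SW480 with ERB at 15.5 and 20.5%.

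The effect of the vector alone was asked by comparing empty vector with parental cells. In the libraries labelled SW480, inflammatory and matrix genes fell. TNFAIP2 was at 4.09 ± 1.7 CPM with empty vector against 224 ± 5.9 in parental SW480 (log2 -5.69, SE 0.44, adjusted p = 1.8e-05, n = 2 and 2), and FN1 at 11.2 ± 3.2 against 560 ± 30 CPM (-5.55, SE 0.35, adjusted p = 8.8e-06). APCDD1, a WNT pathway inhibitor, was at 26.7 ± 4.1 against 848 ± 160 CPM (-4.9), and the cell cycle gene CCND1 at 111 ± 18 against 1090 ± 200 CPM (-3.2). Some gut epithelial genes rose, with HNF4A at 216 ± 27 against 30 ± 2.7 CPM (2.94, SE 0.24, adjusted p = 2.7e-05), VIL1 at 612 ± 8.2 against 107 ± 6.1 CPM (2.6) and the epithelial cadherin gene CDH1 at 89.8 ± 28 against 11.7 ± 4.6 CPM (3.02). The same 309 genes high in parental SW480 stood at 2.13% and 2.05% of their parental level in these libraries.

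Of 17464 genes, edgeR called 5399 in this comparison, 2604 higher and 2795 lower with empty vector. With GC and length offsets the split was 4610 higher and 2851 lower. The 8 largest decreases were in genes with 0 reads with empty vector, among them SAA2 (at least 387-fold lower; its reads are uncertain because of the near-identical copy SAA1), the protease gene CTSS (at least 426-fold), PIP5K1B (at least 315-fold) and CHST2 (at least 261-fold). Among the largest increases were INHBE (66.2 ± 91 against 0.399 ± 0.21 CPM), CHAC1 (178 ± 240 against 2.19 ± 0.98 CPM) and DDIT4 (318 ± 410 against 4.97 ± 0.11 CPM), which are induced by amino acid or endoplasmic reticulum (ER) stress; CHAC1 lost its call without parental library II. Their SDs exceeded the means with empty vector. On levels adjusted for GC content and length, the median of 31 amino acid and ER stress genes was compared with the untreated SW620 mean. It lay 2.14 above that mean on the log2 scale in library II and 0.08 in library I. Of 28 NF-kB targets 18 fell and 0 rose (23 and 0 adjusted over the list alone; median log2 -2.75; camera adjusted p = 4.7e-13, and adjusted p = 0.0017 with an estimated correlation), with CXCL1 at -6 and ICAM1 at -4.56. Of 30 epithelial junction genes 16 rose and 2 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.0014, but adjusted p = 0.078 with an estimated correlation). Of 31 adhesion genes 13 fell and 2 rose (15 and 2 adjusted over the list alone; camera adjusted p = 0.0028, but adjusted p = 0.078 with an estimated correlation), with CYR61 at -5.35. Enterocyte genes (6 of 15 rose, 1 fell; 7 and 2 adjusted over the list alone; camera adjusted p = 0.0028, but adjusted p = 0.084 with an estimated correlation) and secretory genes (6 of 12 rose, 1 fell; 6 and 2 adjusted over the list alone; camera adjusted p = 0.0067, but adjusted p = 0.078 with an estimated correlation) rose. Cytosolic ribosomal protein genes rose as well, 16 of 35 with 0 falling (24 and 0 adjusted over the list alone; camera adjusted p = 2.4e-06, but adjusted p = 0.57 with an estimated correlation), for example RPS4X (1.73) and RPS23 (1.52). Signs of RNA quality moved in the same comparison. Of 13 mitochondrially encoded mRNAs 9 rose and 1 fell (11 and 1 adjusted over the list alone; median 1.28; camera adjusted p = 0.0049, but adjusted p = 0.61 with an estimated correlation), with MT-ND1 at 4260 ± 2600 against 1080 ± 180 CPM (2.07). Of 13 histone genes 6 fell and 2 rose, also over the list alone (median -1.06; camera adjusted p = 0.021, but adjusted p = 0.57 with an estimated correlation). The count was 2122 without parental SW480 library II, 10643 without empty vector library I and 2866 without empty vector library II, and it was 704 when only the 6 SW480 libraries were fitted.

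In SW620, the same comparison set sterol genes apart. The list of cholesterol synthesis genes stood apart with a median log2 difference of 0.59 (camera adjusted p = 1.2e-14, and adjusted p = 0.0049 with an estimated correlation), although 0 of its 25 genes passed the test over all genes and 4 rose when adjusted over the list alone. INSIG1, a sensor of sterols, was at 26.7 ± 5.2 CPM with empty vector against 8.23 ± 0.056 in parental cells (SD, n = 2), and SREBF2, a transcription factor of the pathway, at 253 ± 30 against 106 ± 16 CPM. TAGLN, which encodes an actin-binding protein of smooth muscle, was at 7.05 ± 1.7 against 72.6 ± 29 CPM, and CDH1 at 50.6 ± 0.66 against 16.7 ± 3.2 CPM.

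Over all genes, edgeR called 0 of 17464 in this comparison, with 276 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.67; DESeq2 called 11 and limma-voom 0. When only the 10 SW620 libraries were fitted, with GC and length offsets, a choice made after the values were seen, 94 genes rose and 73 fell. In that fit TAGLN fell (log2 -3.38, SE 0.19, adjusted p = 1.8e-05), as did the neuronal genes CPLX2 (-1.74) and GAP43 (-1.02). DDIT4 (1.78, SE 0.12, adjusted p = 4.9e-05), DPEP1 (1.66), CDH1 (1.53), INSIG1 (1.67) and SREBF2 (1.14) rose. There, 7 of 25 cholesterol synthesis genes rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 4.9e-30, and adjusted p = 0.037 with an estimated correlation). In the fit of 16 libraries, epithelial junction genes had a median of 0.27 (camera adjusted p = 0.0013, and adjusted p = 0.046 with an estimated correlation), with 0 of 30 genes called and 2 rising adjusted over the list alone. Immediate early genes (median 0.35, 0 of 29 called, also over the list alone) had a camera adjusted p of 2.7e-06, but adjusted p = 0.18 with an estimated correlation. Leukocyte markers (median 0.6, 0 of 7 called, 1 rising over the list alone) had a camera adjusted p of 0.0022, but adjusted p = 0.19 with an estimated correlation, and fibroblast markers (median 0.55, 0 of 6 called, also over the list alone) a camera adjusted p of 0.12. In the 10 SW620 libraries alone the fibroblast list, with 4 genes tested, had a camera adjusted p of 0.016, but adjusted p = 0.13 with an estimated correlation. S phase genes (median -0.17, 0 of 35 called, also over the list alone) had a camera adjusted p of 0.005, but adjusted p = 0.38 with an estimated correlation. The count in the 10 libraries was 1760 without parental library I, 50 without empty vector library I and 39 without empty vector library II.

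Whether ERB alone changed expression in SW620 was asked by comparing ERB with empty vector, both without added ligand. ESR2 rose (log2 7.27, SE 0.55, adjusted p = 0.00064, n = 2 and 2), and it was the 1 gene of 17464 that edgeR called. At an unadjusted p under 0.05 there were 94 genes; DESeq2 called 1 and limma-voom 2. None of the 28 tested classical estrogen response genes passed the test, also over the list alone, and their median log2 difference was -0.07 (camera adjusted p = 0.63). The list of steroid and nuclear receptors and coregulators stood apart through ESR2 (1 of 27 rose, also over the list alone; camera adjusted p = 0.0047, but adjusted p = 0.38 with an estimated correlation). Further genes from fits of fewer libraries were chosen after their values were seen. EEF1A2, a translation elongation factor gene, was at 45.7 ± 4.3 against 110 ± 18 CPM (-1.28; adjusted p = 0.0053 in an edgeR fit of these 2 groups alone and 1 in the fit of 16 libraries). CRMP1, a neuronal gene, was at 17 ± 0.1 against 32.7 ± 5.6 CPM (-0.94, adjusted p = 0.034 in the 10 SW620 libraries with GC and length offsets). On simulated counts for this comparison, the fit of 16 libraries recovered 26% of genes changed 4-fold and 90% of genes changed 8-fold. The changed genes were drawn only from those with higher counts, so recovery at low counts was not measured. Without either empty vector library the call of ESR2 was lost.

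In the libraries labelled SW480, the genes that differed most clearly between ERB and empty vector were higher with ERB. TNFAIP2 was at 50 ± 7.4 CPM with ERB against 4.09 ± 1.7 with empty vector (SD, n = 2; log2 3.67, SE 0.4, adjusted p = 0.00088), CYR61 at 47.8 ± 3.9 against 4.89 ± 0.8 CPM (3.35, SE 0.33, adjusted p = 0.00059) and FN1 at 81 ± 33 against 11.2 ± 3.2 CPM (2.9). CDKN1A, the cell cycle inhibitor p21, was at 61.7 ± 13 against 4.99 ± 2.9 CPM (3.69, SE 0.48, adjusted p = 0.0031), and APCDD1 at 147 ± 32 against 26.7 ± 4.1 CPM (2.51). In parental SW480, TNFAIP2 was at 224 ± 5.9, CYR61 at 211 ± 47, FN1 at 560 ± 30, CDKN1A at 81.6 ± 27 and APCDD1 at 848 ± 160 CPM.

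Here edgeR called 192 genes, 192 higher and 0 lower with ERB, with 1688 genes at an unadjusted p under 0.05; with GC and length offsets the split was 399 higher and 182 lower. DESeq2 gave 343 higher and 53 lower. ESR2 was among them (5.73, SE 0.49, adjusted p = 0.00049). The largest increases included the sulfotransferase gene CHST2 (at least 67.4-fold, 0 reads with empty vector), the cystatin gene CST5 (at least 44.8-fold), CST2 (7.08; uncertain because of near-identical cystatin copies), the immune ligand gene CD70 (ratio 122, interval 33.3 to 1010), DPYSL5 (69.4, 23.4 to 339), VSTM1 (59.9, 20.2 to 293) and the potassium channel gene KCNN4 (48.4, 16.3 to 238). The call was lost for CHST2 without ERB library I, for CST5 without ERB library I or II, for CST2 without ERB library I or empty vector library I, and for VSTM1 without any 1 of the 4 libraries. Of the 192 genes, 180 were also called higher in parental SW480 than in parental SW620, where independent lists would share 21, and 2 were called the other way. The parental libraries were in neither group of the ERB comparison, but they shared its filter and its estimate of the spread. Of 28 NF-kB targets 3 rose and 0 fell (6 and 0 adjusted over the list alone; median log2 0.64; camera adjusted p = 6.3e-07, and adjusted p = 0.008 with an estimated correlation), with ICAM1 at 2.32 and the lymphotoxin gene LTB at a ratio of 12.3 (3.06 to 107). In the 6 SW480 libraries alone 0 of these 28 were called, 4 rose over the list alone, and the list had a camera adjusted p of 7.3e-07, but adjusted p = 0.33 with an estimated correlation. Of 23 mesenchymal genes 4 rose and 0 fell (8 and 1 adjusted over the list alone; camera adjusted p = 1.1e-07, but adjusted p = 0.2 with an estimated correlation), among them the actin gene ACTA2 (3.26). Of 29 interferon-stimulated genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0019, but adjusted p = 0.099 with an estimated correlation). These were IFITM1 (at least 15.7-fold), IFI27 (ratio 19.3, 6.29 to 96.3) and OAS1 (1.34). Of 28 classical estrogen response genes 2 rose, OLFM1 (4.3) and KRT13 (4.62), with 3 rising over the list alone (camera adjusted p = 0.11). Amino acid and ER stress genes had a median of -1.22, with 0 of 31 called and 12 falling when adjusted over the list alone (camera adjusted p = 2.1e-06, but adjusted p = 0.46 with an estimated correlation). On levels adjusted for GC content and length, the median of these stress genes in empty vector library II lay 2.14 above the untreated SW620 mean (log2). In empty vector library I it lay 0.08 above. Replication-dependent histone genes had a median of 1.01 (1 of 13 rose, 4 over the list alone; camera adjusted p = 2.8e-05, but adjusted p = 0.23 with an estimated correlation).

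The count of 192 was 89 and 91 without ERB library I or II and 867 without empty vector library II. It was 0 when only the 6 SW480 libraries were fitted, and 126 higher and 0 lower in those libraries with GC and length offsets.

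The ERB effects of the 2 lines were compared directly. ERB minus empty vector was lower in SW620 than in the libraries labelled SW480 for 33 genes and higher for 0 (edgeR, 782 genes at an unadjusted p under 0.05). The difference for ESR2 itself was 1.54 (SE 0.77, adjusted p = 1). NGFR, a neurotrophin receptor gene, was at 415 ± 130 CPM with ERB against 20.2 ± 9.8 with empty vector in the SW480 libraries, and at 21.7 ± 0.074 against 28.8 ± 3.1 CPM in SW620 (difference -4.83, SE 0.56, adjusted p = 0.01). In parental SW480 it was at 811 ± 210 CPM. TRIP6, a zyxin family adaptor gene, was at 68.5 ± 17 against 1.96 ± 1.4 CPM in SW480 and at 0.428 ± 0.17 against 0.449 ± 0.19 CPM in SW620 (-5.28, adjusted p = 0.047). FN1 (-3.64), CYR61 (-3.43), TNFAIP2 (-3.13) and APCDD1 (-2.81) also differed. The NF-kB list differed with a median of -0.62 (0 higher and 1 lower of 28, also over the list alone; camera adjusted p = 0.00015, and adjusted p = 0.04 with an estimated correlation). With offsets the split was 9 higher and 89 lower. The 1 gene called in both lines was ESR2, the transduced gene itself. Without SW620 ERB library I or II the count of 33 was 0 and 0, without SW620 empty vector I or II 7 and 1, without SW480 ERB I or II 12 and 17, and without SW480 empty vector I or II 83 and 91.

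DMSO-treated SW620 cells with ERB were compared with the same cells without treatment, as the background of the estradiol comparison. Some genes of ER and amino acid stress rose. DDIT3, a pro-apoptotic stress transcription factor, was at 116 ± 14 CPM in DMSO against 15.3 ± 2.2 untreated (SD, n = 2; log2 2.92, SE 0.43, adjusted p = 0.0067). ERN1, the ER stress sensor IRE1, was at 66.7 ± 5.4 against 9.08 ± 0.32 CPM (2.87). VEGFA, an angiogenic growth factor on the list of hypoxia and glycolysis genes, rose too (164 ± 15 against 14.7 ± 0.43 CPM, 3.47). Some genes of DNA replication, mitosis and sterol synthesis fell. The replication factor gene GINS2 was at 29.8 ± 5.2 against 154 ± 7.1 CPM (-2.37, SE 0.38, adjusted p = 0.008) and the mitotic kinase gene AURKB at 32.5 ± 3.3 against 229 ± 11 CPM (-2.82).

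Of 17464 genes edgeR called 1074, with 417 higher and 657 lower in DMSO. The largest increases included FAM129A (ratio 271, 48.1 to 10700), the calcium channel gene TRPV6 (164, 55.6 to 796), INHBE (135 ± 8.6 against 1.87 ± 0.45 CPM, 6.16), LAMP3 (5.09) and MAP1B (134 ± 4.7 against 4.2 ± 0.71 CPM, 4.99). The largest decreases included SFRP5, a secreted WNT antagonist (9.44 ± 1.5 against 146 ± 5.7 CPM, -3.96), the deiodinase gene DIO3 (-3.84), FAM178B (-3.67) and the keratin gene KRT5 (-3.39). Of 31 amino acid and ER stress genes 12 rose and 0 fell (21 and 2 adjusted over the list alone; median log2 2.22; camera adjusted p = 2.6e-12, but adjusted p = 0.39 with an estimated correlation). Of 35 S phase genes 16 fell and 0 rose (24 and 0 adjusted over the list alone; camera adjusted p = 1.8e-14, but adjusted p = 0.055 with an estimated correlation). In the 10 SW620 libraries with offsets, both lists held with an estimated correlation (27 rising and 1 falling of 31, and 31 falling of 34, adjusted p = 0.0035 for each). Of 35 mitosis genes 10 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.00019, but adjusted p = 0.39 with an estimated correlation). Of 25 cholesterol synthesis genes 9 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 1.9e-08, and adjusted p = 0.037 with an estimated correlation). Of 26 WNT targets 6 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.00054, but adjusted p = 0.35 with an estimated correlation), among them EPHB2 (-2.25) and BMP4 (-1.77). Hypoxia and glycolysis genes went both ways, with 8 of 30 falling and 2 rising (15 and 5 adjusted over the list alone; camera adjusted p = 0.027, but adjusted p = 0.39 with an estimated correlation), LDHA at -1.53 and EGLN3 at -1.61 among the first and VEGFA among the second. Of 7 leukocyte markers 2 fell and 0 rose (3 and 0 adjusted over the list alone; median -1.58; camera adjusted p = 0.021, but adjusted p = 0.39 with an estimated correlation). Ribosomal protein genes (median -0.46, 0 of 35 called, also over the list alone) had a camera adjusted p of 0.032, but adjusted p = 0.66 with an estimated correlation. The 13 mitochondrially encoded mRNAs, a sign of RNA quality, had a median of -0.56, with 0 called and 1 falling over the list alone (camera adjusted p = 0.077). The DMSO to untreated difference followed transcript GC content across genes (Pearson r -0.54; genes are not independent replicates). The count of 1074 was 13 and 12 without ERB library I or II and 0 and 5 without DMSO library I or II. It was 3631 with GC and length offsets and 8065 in the 10 SW620 libraries alone, where leaving out 1 library gave 4197 to 6102.

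**Figure D3:**
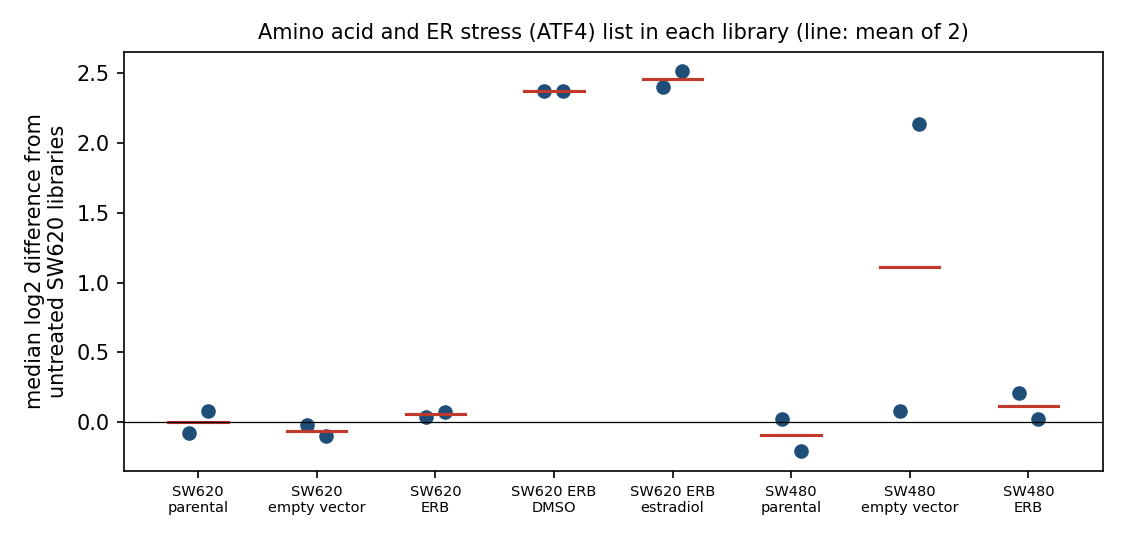
Median log2 difference of 31 amino acid and ER stress genes from the untreated SW620 mean (vertical axis) in each of the 16 libraries (points) by group (horizontal axis), with the mean of 2 libraries as a line. Levels were adjusted for transcript GC content and length. The DMSO and estradiol libraries lie between 2.37 and 2.52 and SW480 empty vector library II at 2.14, and the other libraries between -0.21 and 0.21.

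The response to ligand was asked by comparing estradiol with DMSO in SW620 cells with ERB. The labels do not state whether the estradiol libraries held DMSO too. The mitotic spindle gene ASPM was at 0.409 ± 0.31 CPM after estradiol against 6.38 ± 0.45 in DMSO (SD, n = 2; log2 -3.94) and HMMR at 0.852 ± 0.3 against 10.9 ± 1.3 CPM (-3.68). MIF, a cytokine gene, was at 60.4 ± 21 against 16.8 ± 8.3 CPM (1.84), and CTSD, a known estrogen-induced protease gene, at 188 ± 44 against 67 ± 25 CPM (1.48). None of these passed the test in the fit of 16 libraries, where edgeR called 0 of 17464 genes at a smallest adjusted p of 0.24. There were 3469 genes at an unadjusted p under 0.05; DESeq2 called 72 (3 higher, 69 lower) and limma-voom 1. Mitosis genes (median -0.87, 0 of 35 called, 2 falling over the list alone) had a camera adjusted p of 0.035, but adjusted p = 0.85 with an estimated correlation.

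These differences followed the base composition of the transcripts. GC content and length together took 63.3% of the variance of the estradiol to DMSO difference across genes, and the median difference ran from -1.52 in the decile of lowest GC content to 1.13 in the highest. In the 10 SW620 libraries with GC and length offsets, chosen after the values were seen, 1786 genes were called higher and 1221 lower. ASPM (-2.31, adjusted p = 0.015), HMMR (-2.22, adjusted p = 0.015) and NUF2 (-2.06, adjusted p = 0.017) fell in that fit. MIF rose (0.58, adjusted p = 0.023), as did the ATP synthase subunit genes ATP5L (2.07, adjusted p = 0.015) and ATP5G3 (1.93, adjusted p = 0.016). Of 35 ribosomal protein genes 20 rose and 0 fell (22 and 0 adjusted over the list alone; median 0.59; camera adjusted p = 1.8e-07, but adjusted p = 0.84 with an estimated correlation). Of 32 oxidative phosphorylation genes 18 rose and 0 fell (20 and 1 adjusted over the list alone; camera adjusted p = 2.6e-05, but adjusted p = 0.84 with an estimated correlation), and of 35 mitosis genes 8 fell and 3 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.017, but adjusted p = 0.84 with an estimated correlation). Of 26 classical estrogen response genes 4 rose and 4 fell (4 and 6 adjusted over the list alone; median -0.04; camera adjusted p = 0.76), with CTSD (0.42, SE 0.11, adjusted p = 0.03) and TFF3 (0.65, SE 0.19, adjusted p = 0.036) among the first and MYBL1 (-2.08, SE 0.6, adjusted p = 0.037) among the second. In the fit of 16 libraries this list had 0 of 28 genes called, also over the list alone (median 0.27, 0.14 with genes without reads at their bound; camera adjusted p = 0.75). The count of 3007 in the 10 libraries was 171 without DMSO library I and 0 without DMSO library II or either estradiol library.

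**Figure D4:**
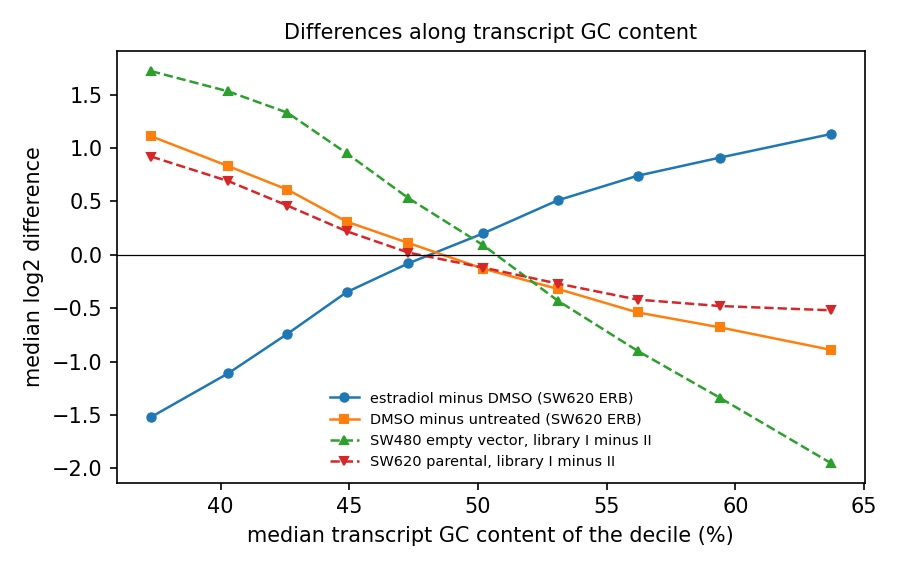
Median log2 difference (vertical axis) of genes in 10 bins of transcript GC content (horizontal axis, percent) for 2 group differences (solid) and the difference of libraries I and II in 2 untreated groups (dashed). Estradiol minus DMSO runs from -1.52 to 1.13 with rising GC content, and the other 3 lines run downward.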

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

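The test of the empty vector effect between the lines and all tests of explanations below were chosen only after the results were seen, while the test of the ERB effect between the lines was planned. By that planned test of the difference itself, the ERB effect in SW620 differed from that in the libraries labelled SW480 for 33 genes and 7 gene lists. The lists were those of amino acid and ER stress, NF-kB, mesenchymal, interferon-stimulated, MHC class I, histone and TGF-beta target genes, and 1 of them, NF-kB, passed with an estimated correlation. The 33 genes became 0 without SW620 ERB library I or II, 7 and 1 without SW620 empty vector library I or II, 12 and 17 without SW480 ERB library I or II, and 83 and 91 without SW480 empty vector library I or II. The largest differences on the log2 scale were those of DPYSL5 (-6.8), DEFA5 (-6.76), CCDC3 (-5.46), TRIP6 (-5.28), KCNJ5 (-5.06), NGFR (-4.83), SCARA3 (-4.81) and DKK3 (-4.71), and each of these 8 lost its call without SW620 ERB library I or II. DEFA5 had 0 reads in SW480 with empty vector, so its value depends on the small count that the fit adds. By the added test, the empty vector effect differed between the lines for 1258 genes, 733 higher and 525 lower in SW620, a split that turned to 1496 higher and 2890 lower with GC and length offsets. That count was 797 and 451 without SW620 parental library I or II, 2345 and 727 without SW480 parental library I or II, 526 and 345 without SW620 empty vector library I or II, and 7778 without SW480 empty vector library I.

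The 309 genes high in parental SW480 stood at medians of 2.13% and 2.05% of that level in the empty vector libraries labelled SW480, with 281 and 262 genes under 10%, and at 15.5% and 20.5% in the ERB libraries. On levels adjusted for GC content and length, the same rule chose 280 genes. Their highest median share in the empty vector libraries labelled SW480 was 3.25%. For that set, the tables argued against GC content and length as the whole cause. A vector response common to both lines stayed open for these 309 genes. The vector effect differed between the lines for 1258 genes, but that count cannot decide for this set. The 309 genes were chosen to be low in parental SW620, so they had little room to fall there. A changed expression state in cells with the chromosome content of parental SW480 stayed open, as neighbouring genes that change state together would move windows too: over 419 windows of 40 neighbouring genes, the empty vector libraries followed the difference of the parental lines with slopes of 0.85 (95% interval 0.69 to 1.01) and 0.84 (0.55 to 1.13), against 0.82 to 0.99 in SW620 libraries that did not serve as the reference and 0.68 (0.4 to 0.96) and 0.71 (0.53 to 0.89) in the ERB libraries labelled SW480. It also stayed open whether the empty vector libraries labelled SW480 hold SW620 cells. On levels adjusted for GC content and length, 5 genes were at 5 CPM or more in all 6 untreated SW620 libraries but over 8-fold below their lowest SW620 level in both. These were CYTL1, TMEM178B, PROM1, ARHGAP22 and SGPP2, at 0 to 1.12 CPM without that adjustment. The number of such genes was 0 in held-out SW620 pairs and 28 in parental SW480. Of the 5 genes, 3 were also that low in parental SW480 and 4 in the ERB libraries labelled SW480. Over log2 CPM of the tested genes, empty vector libraries I and II labelled SW480 correlated at 0.973 and 0.916 with SW620 with empty vector. Their correlations with parental SW480 were 0.882 and 0.773, and with each other 0.893. These values carry the GC trends too and do not tell SW620 cells from a changed state. The vector and ERB comparisons in SW480 therefore cannot be read as effects within a line. A mixture with parental SW480 cells in the ERB libraries was not told apart from an effect of ERB itself. As deviations on the log2 scale, shares of single genes spread by 2.07 and 1.17 in libraries I and II, against 0.88 for the parental ratio. This was 1.33 times as wide in library II but far wider in library I, so the 2 libraries gave no common answer. Single genes such as CST1 lay above the parental level (1310 and 833 against 608 and 191 CPM), which a mixture alone does not give. The reads of CST1 are uncertain, however, because of near-identical cystatin copies. Most shares lay well below it, with upper quartiles of 38.4% and 32.6%.

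The estradiol to DMSO difference followed transcript GC content. The 63.3% of the variance across genes that GC content and length took is this pattern itself, so it says nothing about its cause. Separately, they took up to 59.2% of the variance between libraries I and II of an untreated group. Such a trend thus also arose between libraries of the same treatment, and a technical GC and length bias stayed possible. An estradiol response of the classical estrogen genes stayed open, as their camera adjusted p was 0.76 with offsets and their members went both ways. In the 10 SW620 libraries with offsets 3007 genes were called, 171 without DMSO library I and 0 without DMSO library II or either estradiol library.

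Amino acid and ER stress genes were higher in the DMSO libraries than in untreated ones. The tables argued against GC content and length as the whole cause, since the median log2 difference was 2.33 with offsets. A state of the culture that also arises without DMSO or estradiol stayed possible. On levels adjusted for GC content and length, libraries I and II of SW480 with empty vector differed by a median of -2.21, although this rests on 1 library. The DMSO vehicle itself stayed open, since the list was 2.52 higher in the estradiol libraries than in untreated ones and the labels do not say whether those held DMSO.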

How the results depend on the processing

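The GC and length offsets, the fits of libraries of 1 line, both together, the fit without transduced SW480 libraries, the vector effect between lines and estradiol against no treatment were chosen after seeing the data; the other alternatives were planned. The 71 results for single genes chosen by the naming rule were followed under only some alternatives. These were RLE, DESeq2, limma-voom, the replicate block, GC and length offsets and leaving out libraries. None of the 71 turned its direction under them. Parental cells as control were not among them. With ERB, the libraries labelled SW480 were below parental SW480 in FN1 (81 against 560 CPM) but above it in CD70 (10.8 against 6.55 CPM), for example. With GC and length offsets the balance of higher and lower calls turned for the parental lines (1194 and 1953 to 3530 and 2636), for the vector in SW480 (2604 and 2795 to 4610 and 2851) and for the difference of the vector effects (733 and 525 to 1496 and 2890). Of 675 values of these single genes, 557 stayed on the same side of the threshold, 118 kept their direction but lost the call and 0 gained it. Apart from ESR2, the rule named called genes, so the absence of gains was largely set by that choice. RLE size factors, a filter of 1 CPM in 4 libraries and all settings not given here left the counts of called genes within 1.5 times. With 2 libraries per group the spread rests on 8 degrees of freedom shared by 8 groups, and at depths of 12743940 to 18948283 reads a gene of 0.16 to 0.24 CPM had 3 reads in a library, so absence below that level cannot be seen. The cause of the moves below was not tested. Leaving libraries or whole groups out also removes degrees of freedom by construction. It changes the estimate of the spread too. The common coefficient of variation between libraries of a group was 0.36 in the fit of 16 libraries. It was 0.186 in the 10 SW620 libraries and 0.534 in the 6 SW480 libraries. The shared estimate thus lay above that of SW620 and below that of SW480.

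Counts of called genes moved as follows, from the fit of 16 libraries: ERB in SW620 1, ERB in SW480 192, difference of the ERB effects 33, estradiol against DMSO 0, vector in SW620 0, vector in SW480 5399, parental lines 3147, DMSO against no treatment 1074, difference of the vector effects 1258 and estradiol against no treatment 302. DESeq2 gave 396 for ERB in SW480, 115 for the difference of the ERB effects, 72 for estradiol, 11 for the vector in SW620 and 2656 for DMSO. With limma-voom there were 2 for ERB in SW620, 374 for ERB in SW480, 51 for the difference and 1 for estradiol. No low-count filter gave 4 for ERB in SW620, 800 for ERB in SW480, 131 for the difference, 1949 for estradiol, 15 for the vector in SW620 and 2843 for DMSO. On log2(FPKM + 1) there were 4 for ERB in SW620, 56 for the difference, 17 for estradiol and 3 for the vector in SW620, and without a filter 17, 116, 160 and 23, with 1871 for DMSO. On log2(FPKM + 0.1) there were 3 for ERB in SW620, 6 for estradiol, 3 for the vector in SW620 and 3521 for the vector in SW480. A fit of only the groups of the comparison gave 3 for ERB in SW620, 0 for ERB in SW480, 0 for the difference, 10111 for estradiol, 1217 for the vector in SW480, 1482 for the parental lines and 10285 for DMSO. Parental cells as control gave 7756 for ERB in SW480, and the lines compared through their empty vector libraries gave 57.

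Among alternatives chosen after seeing the data, GC and length offsets gave 581 for ERB in SW480, 98 for the difference of the ERB effects, 15 for the vector in SW620, 6166 for the parental lines, 3631 for DMSO, 4386 for the difference of the vector effects and 2757 for estradiol against no treatment. Libraries of the same line only gave 0 for ERB in SW480, 8759 for estradiol against DMSO, 14 for the vector in SW620, 704 for the vector in SW480, 8065 for DMSO and 3455 for estradiol against no treatment. With offsets in these libraries there were 2 for ERB in SW620, 126 for ERB in SW480, 3007 for estradiol, 167 for the vector in SW620, 3397 for the vector in SW480 and 7629 for DMSO. Without the transduced SW480 libraries the parental lines gave 5571.

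Called lists numbered 1 for ERB in SW620, 7 for ERB in SW480, 7 for the difference of the ERB effects, 2 for estradiol, 13 for the vector in SW620, 12 for the vector in SW480, 10 for the parental lines and 10 for DMSO. In that order an estimated inter-gene correlation left 0, 1, 1, 0, 2, 1, 4 and 1. For estradiol, log2(FPKM + 1) gave 1 list, GC and length offsets 5 and libraries of the same line only 1.

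The numbers I and II are not stated to mark a shared batch. Deviations of libraries with the same number correlated over 0.1 in 9 of 28 pairs of groups and below -0.1 in 12 (-0.74 to 0.66), without a common direction. These deviations also followed transcript GC content, with Pearson r from -0.75 to 0.66 by group. They therefore do not show whether the numbers mark a shared culture or day. A replicate block gave 16 for the difference of the ERB effects and 555 for DMSO. The other counts stayed within 1.5 times, at 1 for ERB in SW620, 143 for ERB in SW480, 0 for estradiol, 0 for the vector in SW620, 4093 for the vector in SW480 and 2570 for the parental lines. Lists under the block were 0 for ERB in SW620 and 1 for estradiol.

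Leaving out each library in turn gave 0 to 1 for ERB in SW620, 89 to 867 for ERB in SW480, 0 to 91 for the difference of the ERB effects, 0 to 1 for estradiol, 0 to 0 for the vector in SW620, 2122 to 10643 for the vector in SW480, 1358 to 3910 for the parental lines, 0 to 13 for DMSO, 345 to 7778 for the difference of the vector effects and 0 to 3 for estradiol against no treatment. In the SW620 libraries it gave 1 to 1 for ERB, 0 to 6390 for estradiol, 0 to 326 for the vector and 4197 to 6102 for DMSO, and with offsets 1 to 3, 0 to 171, 39 to 1760 and 5433 to 5628. Genes shared by both ERB comparisons were 0 to 1, and those shared by ERB and estradiol in SW620 0 to 0. Lists were 0 to 3 for ERB in SW620, 6 to 14 for ERB in SW480, 6 to 12 for the difference, 1 to 3 for estradiol, 6 to 10 for the vector in SW620, 8 to 14 for the vector in SW480, 8 to 10 for the parental lines and 7 to 10 for DMSO.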

Other observations

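Genes of other hormone receptors and of estrogen metabolism set the parental lines apart without forming a called list. GPER1, a membrane estrogen receptor gene, was at 77.2 ± 15 CPM in SW620 against 9.2 ± 1.2 in SW480 (SD, n = 2; log2 3.11, SE 0.41, adjusted p = 0.00035 by edgeR). HSD17B2, whose product oxidizes estradiol to estrone, was at 2.55 ± 0.22 against 20.2 ± 5.8 CPM (-2.95, SE 0.42, adjusted p = 0.00051), and the nuclear receptor gene NR2F2 at 19 ± 5.5 against 94.6 ± 9.5 CPM (-2.28). Of 27 receptors and coregulators 3 rose and 7 fell (camera adjusted p = 0.16), and of 12 estrogen metabolism genes 2 rose and 2 fell (camera adjusted p = 0.71). Of 30 hypoxia and glycolysis genes 2 rose and 6 fell, also over the list alone (median log2 0.23; camera adjusted p = 0.55), with NDRG1 (2.43 ± 1.5 against 175 ± 53 CPM, -6.14) and SLC2A3 (19.2 ± 2.4 against 922 ± 15 CPM, -5.55) among those that fell and CA9 (4.79) among those that rose. In the DMSO comparison of SW620 with ERB, GPER1 fell (9.2 ± 3 against 44.3 ± 2 CPM, -2.27), as did the calcium-binding protein gene S100A4 (249 ± 42 against 1830 ± 130 CPM, -2.88), and the cell cycle inhibitor gene CDKN2B rose (33.1 ± 0.69 against 5.44 ± 0.02 CPM, 2.6).

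Estradiol-treated SW620 cells with ERB were also compared with untreated ones, a contrast chosen after seeing the data. DMSO against the same untreated libraries moved the lists in the same direction. Its median log2 differences were 2.22 for stress, -1.38 for S phase, -1.24 for cholesterol synthesis and -0.6 for mitosis genes. The changes below therefore cannot be assigned to estradiol. Amino acid and ER stress genes rose, 10 of 31 with 0 falling (25 and 0 adjusted over the list alone; median log2 2.51; camera adjusted p = 1.2e-25, but adjusted p = 0.14 with an estimated correlation). S phase genes fell, 4 of 35 with 0 rising (0 rising and 25 falling over the list alone; median -1.12; camera adjusted p = 1.2e-19, and adjusted p = 0.024 with an estimated correlation), as did 5 of 25 cholesterol synthesis genes with 0 rising (8 falling over the list alone; median -0.87; camera adjusted p = 1e-08, and adjusted p = 0.024 with an estimated correlation). Of 35 mitosis genes 2 fell and 0 rose (18 falling over the list alone; median -1.41; camera adjusted p = 3.6e-18, but adjusted p = 0.11 with an estimated correlation). In the 10 SW620 libraries alone these 4 lists passed with an estimated correlation as well: 28 of 31 stress genes rose (adjusted p = 0.0021), and 31 of 35 S phase genes (adjusted p = 0.0036), 14 of 25 cholesterol synthesis genes (adjusted p = 0.018) and 32 of 35 mitosis genes (adjusted p = 0.036) fell. Of 26 WNT targets 2 fell and 1 rose (8 and 1 over the list alone; median -0.76; camera adjusted p = 2.6e-05, but adjusted p = 0.16 with an estimated correlation). Mitochondrially encoded mRNAs, a sign of RNA quality, had 1 of 13 falling and 0 rising, also over the list alone (median -0.46; camera adjusted p = 0.018, but adjusted p = 0.71 with an estimated correlation). Leukocyte markers had 2 of 7 falling and 0 rising, also over the list alone (median -0.76; camera adjusted p = 0.018, but adjusted p = 0.45 with an estimated correlation). In all 302 genes were called, 185 higher and 117 lower. The count was 2 and 0 without ERB library I or II and 0 and 3 without estradiol library I or II, while it was 2757 with GC and length offsets and 3455 in the 10 SW620 libraries alone.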
